A study of Carassius gibelio with 4 samples.

How the data were processed

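RNA from the liver of gibel carp (Carassius gibelio), a cyprinid fish farmed in East Asia, was sequenced in 4 libraries. They came from 2 strains, called A and F in the labels, each fed a fishmeal diet or a rapeseed meal diet and sampled 8 hours after the last feeding. Each combination of strain and diet is represented by 1 library. The labels do not say how many fish went into a library, so a difference between 2 libraries has no replicate check.

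The authors deposited 1 table per library with a value for each of 56011 gene IDs, in the same order in every table. Per the labels' protocols, liver was frozen in liquid nitrogen, RNA was taken with Trizol and Illumina libraries were made. Bowtie 1.0.1 and RSEM 1.2.17 are named in the submitters' processing notes, without their roles. The reference or assembly that reads were aligned to is not given in the sources used here. The unit was read from the values: the deposited values behave as FPKM (fragments per kilobase of transcript and per fixed number of mapped fragments) multiplied by 1 factor per library. Among values under 3, 100% lay within 0.0006 of a whole multiple of a fixed step in every library (9.0 to 17.0% would by chance), as for numbers of 2 decimals that were rescaled. The steps gave library factors of 0.993 (strain A, fishmeal), 1.34 (strain A, rapeseed), 0.705 (strain F, fishmeal) and 1.07 (strain F, rapeseed), whose product was 1. With the factors divided out, the values summed to 1.23e+06, 1.24e+06, 1.27e+06 and 1.21e+06, above the fixed total of TPM. Before the pseudocount, the factors add 0.43 to every log2 fold of rapeseed over fishmeal in strain A and 0.60 in strain F. They add -0.49 to strain F over strain A on fishmeal and -0.32 on rapeseed. Main values use the deposited scale, and splits without the factors are given for each pair of libraries over all IDs and at mean level 100 or more. For the split over all IDs, a mean level of 1 was required again after the division, which kept 33290 IDs. Splits by level without the factors keep the level classes of the deposited scale, so the 2 kinds do not add up. Such a split shows what the scale sets, and does not show which scale is right.

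The gene IDs have the form c, a number, g and a number. The files do not pair them with gene names, and 0 IDs matched the gene table of the reference assembly used for names. The lists of metabolic, immune and cell type genes fixed before the data were examined could therefore not be applied, and no gene function is reported. IDs with the same c number are taken here to belong to 1 assembly component, as the naming implies. Every value of 0 is the table's own and is reported as listed at 0.

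Absolute depth is unknown, but relative depth could be read from low values, which are whole multiples of what 1 read is worth for that ID. Among 1930 IDs whose values in strain A fishmeal, strain A rapeseed and strain F rapeseed stood at 1, 2 or 3 times the lowest of them, with at least 1 at 2 times (within 0.06 on the log2 scale), the strain F fishmeal library was above 0 in 163. The largest cluster of its values stood at 54.7 times the 1-read unit of the other libraries. It held 48 of the 163, with 18 near 54.7 divided by 2 and 9 near 54.7 divided by 3. Most of the rest lay lower, and their source was not examined. The 1930 IDs were also picked within a fixed range of low values. On simulated reads with a depth ratio of 40 the procedure returned 40.1. By this estimate the strain F fishmeal library had 1 read for every 54.7 in the others. The modal ratio of low values put strain A rapeseed at 1 and strain F rapeseed at 1.02 times the depth of strain A fishmeal. Values rounded to 2 decimals often tie at a ratio of 1, and with values over 2 alone the ratios were 0.983 and 1.02. The mode was sought only among ratios near 1, so a larger difference of depth could not have been returned.

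Folds were differences of log2(value + 1) and understate the change of low IDs. IDs with a mean of 1 or more over the 4 libraries were kept (35517 IDs). With 1 library per group, differences were described by a fixed rule of size, at least 2-fold, with no p-value. Agreement between the 2 diet pairs, or between the 2 strain pairs, which share no library, was set against the overlap of independent lists. An additive model of strain and diet over the 4 libraries, fitted with limma 3.58.1 (eBayes with a trend on level, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, leaves 1 residual degree of freedom. Its spread is the difference of the diet response between the strains, pooled over IDs of a like level. In the main fit limma used that pooled spread alone, so an ID's own difference between the strains did not enter its p-value. The p-values treat the strains as replicates of the diet and measure only the spread between these 4 libraries. Other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

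The IDs named are those with the largest fold, at most 2 higher and 2 lower per comparison, at a mean level of 10 or more, by a rule fixed before the data were examined. For a contrast over both pairs they also had to be 2-fold apart the same way in both. The 3 IDs of highest level were chosen after their values were seen. The rule and limma were checked on simulated levels for the diet contrast, with 35517 IDs of which 200 changed 8-fold and a log2 noise of 0.30. The 2-fold rule in both strains recovered 100% of them with 6 unchanged IDs called, and limma recovered 100% with 9. That noise is below the spread of folds in these libraries (SD 0.81 and 1.53 for the diet pairs), so it checks the code and not the error rate in these data. Alternatives were the scaling between libraries (median-of-ratios, or a trimmed mean of M values with 30% and 5% trimmed), pseudocounts of 0.1 and 5, no filter or a mean level of 10, a 4-fold limit and limma without the trend. Alternatives chosen after seeing the data were a mean level of 100, the factors divided out, scaling on IDs of mean level 100 or more, a filter without the shallow library, limma without that library, and sums per component. Counting models were not used because the values are not counts.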

Results

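The study asked how the liver transcriptome of 2 strains of gibel carp responded to a rapeseed meal diet in place of a fishmeal diet. The data were 4 liver libraries, 1 per combination of strain and diet. Of 56011 gene IDs, 47201 were above 0 in strain A on fishmeal, 44906 in strain A on rapeseed, 47839 in strain F on rapeseed and 19015 in strain F on fishmeal. The strain F fishmeal library was the shallow one: by the estimate above, 1 of its reads was worth 54.7 times as much as 1 read in the others. The depths of the others were estimated at 0.983 to 1.02 times that of strain A on fishmeal, by a search limited to ratios near 1. For the 1930 short or weakly expressed IDs on which this was measured, 1 read in that library would amount to a median of 32.8 FPKM on the deposited scale (5th to 95th percentile 20.8 to 67.5). These IDs were picked within a fixed range of low values, which bounds the percentiles. Over all IDs above 0 in that library the median was 7.69 FPKM and the lowest value 0.261, so the range does not hold for every ID. Both pairs that hold this library, diet in strain F and strain on fishmeal, carry that counting error.

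**Figure D1:**
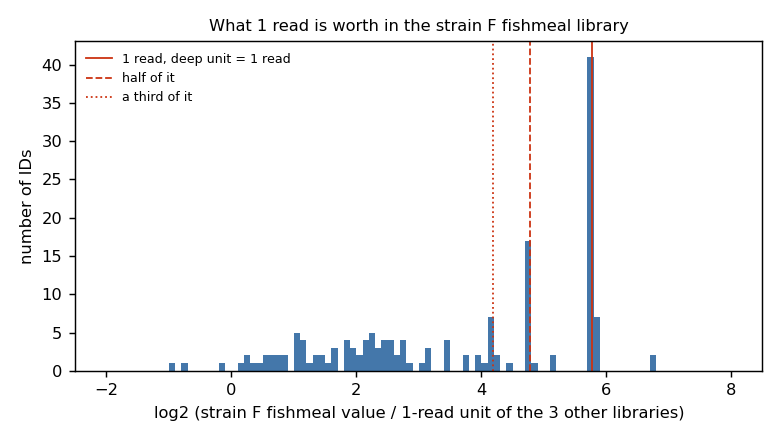
Histogram of the strain F fishmeal value divided by the 1-read unit of the 3 other libraries (log2, horizontal axis) against the number of IDs (vertical axis), for the 163 of 1930 IDs above 0 in that library; lines mark 54.7 times the unit and fractions of it. The highest bars stand at the 54.7-fold line, with 48 IDs within 0.15 of it on the log2 scale.

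The IDs c33686_g1, c29002_g1 and c31665_g4 had the highest mean levels. c33686_g1 stood at 104651 FPKM in strain A on fishmeal, 114029 in strain A on rapeseed, 69132 in strain F on fishmeal and 94230 in strain F on rapeseed. c29002_g1 stood at 102852, 128483, 48060 and 80325 FPKM in the same order, and c31665_g4 at 70225, 74332, 37633 and 48816 FPKM. In strain F on rapeseed c26954_g1, at 50725 FPKM, stood above c31665_g4. The top 3 IDs of each library held 22.8%, 19.2%, 17.3% and 17.5% of its summed level, and the top 100 held 54.2%, 57.9%, 49.4% and 53.0%. Across the 957 IDs of mean level 100 or more, log2 levels correlated between the diets of a strain with Pearson r of 0.91 in strain A and 0.86 in strain F (Spearman 0.86 and 0.85). Between strains on the same diet r was 0.64 on fishmeal and 0.77 on rapeseed (Spearman 0.76 and 0.82). Over all 35517 IDs the order differed, with r of 0.89 between the diets in strain A, 0.82 between the strains on rapeseed, 0.69 between the diets in strain F and 0.59 between the strains on fishmeal. These are correlations across IDs, which are not independent replicates.

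The diet response of strain A compared libraries of similar estimated depth, with 8810 IDs listed at 0 on fishmeal and 11105 on rapeseed. Of 35517 IDs, 2834 were at least 2-fold higher and 2751 at least 2-fold lower on rapeseed. The balance differed by level. Among IDs of mean level 1000 or more, 26 of 183 were 2-fold higher and 0 were 2-fold lower, with a median log2 fold of 0.49. Among IDs of level 100 to 1000, 113 were higher and 19 lower, among IDs of level 10 to 100, 388 and 239, and among IDs of level 1 to 10, 2307 and 2493. The IDs with the largest higher folds by the fixed rule were c12517_g1, at 0.774 FPKM on fishmeal and 147 on rapeseed (log2 fold 6.39), and c29252_g2, listed at 0 on fishmeal and at 70.9 FPKM on rapeseed. Those with the largest lower folds were c31411_g1 and c31411_g2, IDs of one component, from 53.2 to 0.147 FPKM (log2 fold -5.56) and from 142 to 2.42 FPKM (log2 fold -5.39). With 1 library per diet the fold has no replicate check. With the library factors divided out, 1442 of the 33290 IDs then kept were higher and 4364 lower. In the deposited level classes, 82 IDs of level 100 or more were then higher and 42 lower, in place of 139 and 19 (at 1000 or more, 12 and 3). At level 10 to 100 the split turned from 388 and 239 to 229 and 576.

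In strain F, 14493 IDs were at least 2-fold higher and 4907 lower on rapeseed. Of the 14493, 12547 were listed at 0 in the shallow fishmeal library. Among IDs of level 100 to 1000, 204 were higher and 24 lower, and among IDs of level 1000 or more, 19 and 1. The largest folds by the rule all met a 0 in 1 library. c29712_g2 and c17913_g1 were listed at 0 on fishmeal and stood at 294 and 159 FPKM on rapeseed, while c17913_g1 had 127 and 129 FPKM in the 2 strain A libraries. c29712_g1, an ID of the same component as c29712_g2, stood at 62.5 FPKM on fishmeal and 567 on rapeseed in strain F. c43983_g1 and c47851_g1 were listed at 0 on rapeseed and at 88.3 and 84.3 FPKM on fishmeal. Those fishmeal levels lie within 1.5 times the 95th percentile estimated for 1 read in the 1930 IDs used for depth. The number of reads behind them is not known. With the library factors divided out, the split over the 33290 IDs then kept was 11726 higher and 7347 lower. In the deposited level classes it was 69 and 44 at level 100 or more, in place of 223 and 25 (at 1000 or more, 5 and 4). At level 10 to 100 it turned from 1177 and 816 to 603 and 1376.

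The distance of the shallow library from the others varied with level. Among IDs whose levels in the 3 deep libraries lay within 1.5-fold of each other, the share that stood at least 2-fold away from them in the strain F fishmeal library was 52.8% at level 1 to 10 (3817 of 7235), 21.9% at level 10 to 100, 21.0% at level 100 to 1000 and 7.53% at level 1000 or more (7 of 93). The last class had a median log2 difference of -0.73 with an SD of 0.21 over its 93 IDs. With the library factors divided out, that median was -0.05 and the shares of the same IDs were 58.4%, 22.2%, 2.92% and 0%, in the order of rising level.

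**Figure D2:**
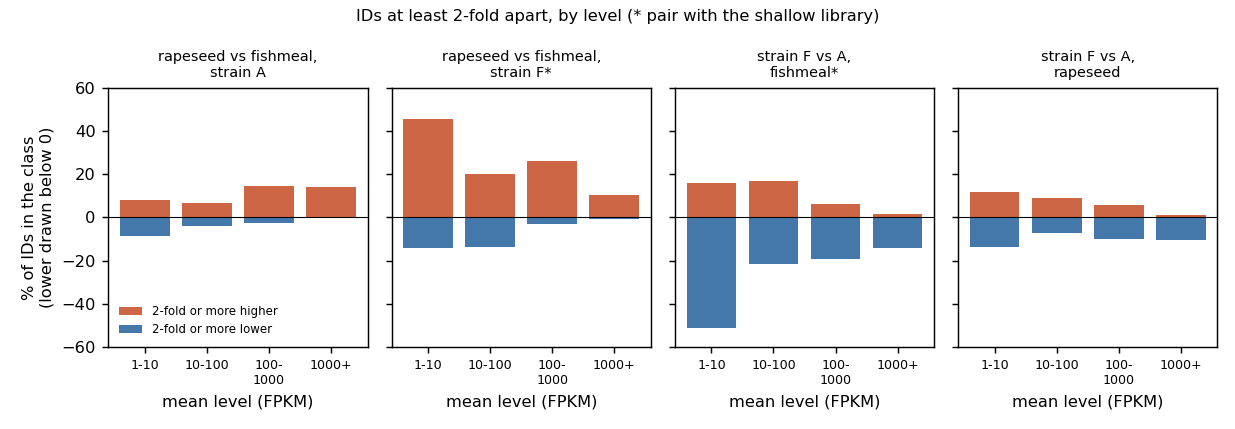
Share of IDs in each class of mean level (horizontal axis, FPKM) that were at least 2-fold higher (above 0) or lower (below 0) in each of the 4 pairs of libraries; the vertical axis is in percent of the class, and asterisks mark pairs with the shallow library. At level 1 to 10, 59.8% of IDs were 2-fold apart in the strain F diet pair and 16.7% in the strain A diet pair.

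The diet pairs of the strains share no library, so IDs that moved alike in both are a comparison across strains. Over all 35517 IDs, 1620 were at least 2-fold higher on rapeseed in both strains, against 1156 for independent lists, and 327 lower in both, against 380. A lower level in strain A with a higher one in strain F was seen in 1508, against 1123, and the reverse in 250, against 392. At level 10 or more, 222 IDs were higher in both, against 108, and 107 lower in both, against 31.8. There 118 were higher in strain A and lower in strain F, against 64.9, and the reverse was seen in 32, against 52.9. At mean level 100 or more, a limit chosen after seeing the data, 69 of 957 IDs were at least 2-fold higher on rapeseed in both strains and 5 were lower in both, where independent lists would share 32.4 and 0.50. Their median log2 fold was 2.03 in strain A and 1.83 in strain F for the 69, of which 7 were listed at 0 in the shallow library, and -2.26 and -1.28 for the 5. With the factors divided out, 33 were higher and 13 lower in both, against 5.91 and 1.93 for independent lists. At level 1000 or more, 9 IDs were higher in both, with log2 folds of 1.05 to 3.63 in strain A and 1.19 or more in strain F, where 1 of the 9 was listed at 0 on fishmeal. With the factors divided out, 12 IDs of that level were higher in strain A and 5 in strain F, so at most 5 could be higher in both. By the rule, c31348_g1 and c23482_g1 were the IDs with the largest higher folds in both strains. c31348_g1 differed in strain A from 81.9 to 919 FPKM, and in strain F it was listed at 0 on fishmeal and at 140 FPKM on rapeseed. c23482_g1 was 76.2 times higher in strain A (1.35 to 103 FPKM) and 37.4 times higher in strain F (2.28 to 85.2 FPKM). The largest lower folds were of c10154_g1, at 6.81 FPKM in strain A and 66.8 in strain F on fishmeal, and c10781_g1, at 3.34 and 65.4 FPKM, both listed at 0 on rapeseed in both strains. The strain F fishmeal values of c10154_g1 and c10781_g1 lie within the range estimated for 1 read in the 1930 IDs used for depth. The number of reads behind them is not known.

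Over all 35517 IDs the diet folds of the strains correlated with Pearson r of 0.05 and Spearman rho of 0.04. Of these IDs, 28686 were of level 1 to 10. At that level, 52.8% of the IDs within 1.5-fold in the deep libraries stood 2-fold away in the strain F fishmeal library. A low r over all IDs therefore cannot tell unrelated responses from counting error in that library. At level 100 or more r was 0.40 and rho 0.27. Opposite responses at that level were, in total, about as many as independent lists would give. A higher level in strain A with a lower one in strain F was seen in 9 IDs, against 3.63 for independent lists, and the reverse in 1, against 4.43. The largest differences of response by the rule again rested on the shallow library. c2526_g1 and c37756_g5 were lower on rapeseed in strain A (61.3 to 10.1 and 46.4 to 2.66 FPKM) and in strain F were listed at 0 on fishmeal and at 37.5 and 15.2 FPKM on rapeseed. c48688_g1 and c19401_g1 were listed at 0 on fishmeal in strain A and on rapeseed in strain F, with 4.77 and 4.49 FPKM in strain A on rapeseed and 68.2 and 64.1 FPKM in strain F on fishmeal. No test of the difference is possible with 1 library per cell of the design, since it uses every degree of freedom.

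On rapeseed, where both libraries were deep, strain F differed from strain A by at least 2-fold in 8356 IDs, 3931 higher and 4425 lower. At level 1000 or more 2 were higher and 19 lower, and at level 100 to 1000, 44 and 78, while at level 10 to 100 it was 527 and 420. With no filter on level the split was 8102 higher and 6626 lower. The largest folds were between levels and listed zeros. c29712_g1 and c43908_g1 were listed at 0 in strain A on both diets and stood at 567 and 293 FPKM in strain F on rapeseed and at 62.5 and 186 FPKM on fishmeal. The component of c29712_g1 was not absent from strain A, where c29712_g2 stood at 43.4 FPKM on fishmeal and 68.5 on rapeseed. c33007_g1 and c35651_g6 were listed at 0 in strain F on both diets and stood at 481 and 362 FPKM in strain A on rapeseed and at 447 and 242 FPKM on fishmeal. With the library factors divided out the split over the 33290 IDs then kept was 4719 higher and 2801 lower. In the deposited level classes it turned at level 100 or more from 46 and 97 to 70 and 60 (at 1000 or more, 3 and 15).

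On fishmeal, strain F stood at least 2-fold above strain A in 5570 IDs and below it in 16158. At level 1000 or more the numbers were 3 and 26. c32500_g3 and c32500_g2, of one component, were listed at 0 and at 0.467 FPKM in strain A and at 2474 and 1539 FPKM in strain F. On rapeseed they stood at 3.10 and 3.06 FPKM in strain A and at 670 and 419 FPKM in strain F. c21365_g1 went the other way, with 3409 FPKM in strain A and a listed 0 in strain F on fishmeal, and 9168 against 107 FPKM on rapeseed, 85.8 times lower in strain F. c33007_g1 had the next largest lower fold. With the library factors divided out, 7531 of the 33290 IDs then kept were higher and 13701 lower. In the deposited level classes, the split at level 100 or more turned from 51 and 177 to 95 and 75 (at 1000 or more, 6 and 11). At level 10 to 100 it turned from 986 and 1263 to 1446 and 798.

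Strain differences on the 2 diets were compared in the same way. Over all 35517 IDs, 1312 were at least 2-fold higher in strain F on both diets and 3447 lower, against 616 and 2013 for independent lists. At level 10 or more the split turned, with 405 higher and 321 lower, against 87.0 and 109. At level 100 or more, 32 IDs were 2-fold higher in strain F on both diets and 57 lower, against 2.45 and 17.9 for independent lists. The 32 had median log2 folds of 6.47 on fishmeal and 4.50 on rapeseed, and the 57 of -2.30 and -2.18. Of the 57, 9 were listed at 0 in the shallow library. The folds on the 2 diets correlated with Pearson r of 0.79 and Spearman rho of 0.48 across these IDs, and with r of 0.36 and rho of 0.30 across all 35517. With the factors divided out, 44 were higher and 37 lower on both diets, against 6.95 and 4.70. The largest on both diets by the rule were c32500_g3 and c8588_g1, the latter at 882 FPKM on fishmeal and 242 on rapeseed in strain F against 0.735 and a listed 0 in strain A, and, lower, c21365_g1 and c33007_g1. Whether the strain and diet contrasts differ in how often they recur was not tested.

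**Figure D3:**
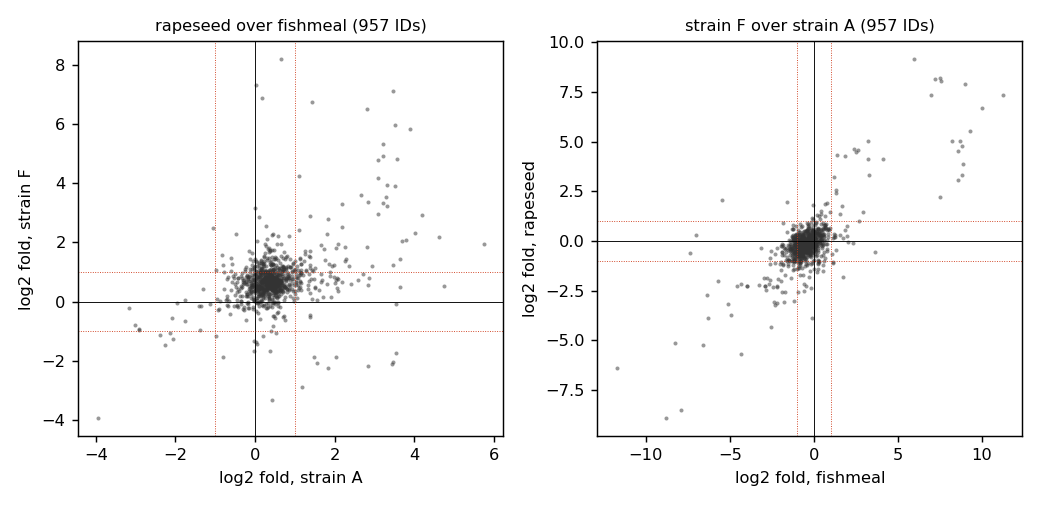
Log2 folds of the 957 IDs of mean level 100 or more, each point an ID: left, rapeseed over fishmeal in strain A (horizontal) and strain F (vertical); right, strain F over strain A on fishmeal (horizontal) and rapeseed (vertical), with dotted lines at 2-fold. Pearson r is 0.40 on the left and 0.79 on the right.

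The additive limma fit over the 4 libraries, with 1 residual degree of freedom, called 516 IDs for diet at an adjusted p under 0.05, 418 higher and 98 lower on rapeseed. It called 1235 for strain, 573 higher and 662 lower in strain F. The fit used the deposited scale, whose library factors raise folds of rapeseed over fishmeal and lower those of strain F over strain A. It was not run with the factors divided out, so how far these splits depend on them is not known. Those counts rest on the spread along the trend, which limma used alone in this fit, so IDs of a like level had the same spread. An ID could therefore be called for diet without a like response in both strains. c17913_g1 was called with log2 folds of 0.02 in strain A and 7.32 in strain F, where it was listed at 0 on fishmeal. Without the trend limma called 0 IDs for diet, with 1958 at an unadjusted p under 0.05 where 1776 would be by chance, and 382 for strain, 241 higher and 141 lower. Without the strain F fishmeal library, limma can fit only 1 of the terms and 1 arm holds 1 library, so its counts over 40089 IDs are not comparable with those above. Strain alone gave 0 calls with 4851 at an unadjusted p under 0.05, and diet alone 0 with 1487, where 2004 would be by chance.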

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

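All tests in this part were chosen after the results were seen. Of the IDs named above, 11 had 2-fold or larger differences of opposite sign in the 2 strains or on the 2 diets, and none of these differences was tested. For diet, the log2 fold in strain F minus that in strain A was -7.93 for c12517_g1, -8.48 for c19401_g1, -8.64 for c48688_g1, 7.76 for c2526_g1, 7.72 for c37756_g5, -3.34 for c32500_g2 and -3.92 for c32500_g3. For strain, c12517_g1, c19401_g1, c2526_g1, c37756_g5 and c48688_g1 also had 2-fold or larger folds of opposite sign on the 2 diets. Other IDs did so for strain alone. Their log2 fold on rapeseed minus that on fishmeal was 7.56 for c29712_g2, 3.96 for c31411_g1, 4.43 for c31411_g2 and -6.12 for c43983_g1. Every one of them includes the strain F fishmeal library, and c19401_g1, c2526_g1, c29712_g2, c32500_g3, c37756_g5, c43983_g1 and c48688_g1 each hold a listed 0 in 1 or more libraries, so their differences depend on the pseudocount.

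In the strain F diet pair, 74.7% of the 2-fold IDs were higher on rapeseed. Lower depth of the strain F fishmeal library is a candidate explanation: 86.6% of the higher IDs were listed at 0 in it, against 30.2% of the higher IDs listed at 0 in the fishmeal library of the strain A pair. At mean level 100 or more, where zeros were few, 89.9% of the 2-fold IDs were higher, and 61.1% (69 higher, 44 lower) with the library factors divided out. Dividing them out shifts every fold of the pair by -0.60 alike before the pseudocount, so the lower share does not show that the factors caused the excess, and a diet response of these IDs stays open.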

How the results depend on the processing

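Settings chosen after seeing the data were a mean level of 100, the factors divided out, scaling on IDs of that level, the filter or limma without the strain F fishmeal library, and sums per component. Counts are given for diet in strain A, diet in strain F, strain on fishmeal, strain on rapeseed, diet in both strains and strain on both diets, in that order, where the main counts were 5585, 19400, 21728, 8356, 1947 and 4759. A pseudocount of 5 gave 1091, 5713, 6781, 1835, 258 and 810. A mean level of 10 or more gave 785, 2241, 2477, 1090, 329 and 726, and one of 100 or more 158, 248, 228, 143, 74 and 89. A 4-fold limit gave 1403, 7415, 9186, 2762, 191 and 1023. A pseudocount of 0.1 moved diet in strain A to 9200, diet in both strains to 3654 and strain on both diets to 7261, and no filter moved diet in strain A to 10245 and strain on rapeseed to 14728. All other counts stayed within 1.5 times, among them those under 4 other scalings and per component. Splits were less steady. The share higher fell from 50.7% to 24.8% for diet in strain A and from 83.2% to 53.2% for diet in both strains with the factors divided out, and to 27.5% and 55.0% with scaling on IDs of level 100 or more. With a pseudocount of 5 it fell from 74.7% to 52.0% for diet in strain F and rose from 25.6% to 48.7% for strain on fishmeal. At a mean level of 10 it turned from 27.6% to 55.8% for strain on both diets, rose from 50.7% to 67.1% for diet in strain A, and fell from 83.2% to 67.5% for diet in both strains. Other splits also moved by over 10 points. In limma, diet calls went from 516 of 35517 IDs to 0 without the trend (1958 IDs at an unadjusted p under 0.05). At level 100 or more they were 120 of 957 IDs, a larger share. Strain calls went from 1235 to 382 and 120 under the same settings. In both settings an ID's own spread also entered its p-value, unlike in the main fit, so the counts are not a like comparison. The fits without the strain F fishmeal library have another form and are not set beside these counts. The correlation of the diet responses rose from 0.05 to 0.17 at level 10 or more, 0.40 at level 100 or more and 0.39 there with the factors divided out. The 28 named folds, taken as the mean of the pairs where both pairs count (and as their difference for the diet response), kept direction and 2-fold size in all 112 combinations of ID and setting tried. They were picked for their size in the same data, so this outcome was close to fixed and is no check of them. Pair by pair, 31 of 32 combinations were 2-fold in both, and c10781_g1 was -0.74 in strain A with a pseudocount of 5. With a library left out, the fit of strain and diet together has no residual degrees of freedom, so without the strain F fishmeal library only 1 term was fitted, with 1 library in 1 arm, and the other libraries were not left out. Gene list medians were not run because the IDs have no names. A higher level and a stricter limit pass fewer IDs by construction, and for the other moves the cause was not tested.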

Other observations

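All tests in this part were chosen after the results were seen. A set of IDs was limited to 1 strain. At 10 FPKM or more in both strain A libraries and listed at 0 in the strain F rapeseed library were 57 IDs (median of their highest level 33.1 FPKM, up to 481). The same pattern around the other deep libraries, a 0 in 1 and 10 or more in both others, gave 5 IDs for strain A on fishmeal and 0 for strain A on rapeseed. In the other direction, 66 IDs stood at 10 FPKM or more in strain F on rapeseed (up to 567) and were listed at 0 in both strain A libraries, against 3 IDs for each strain A library alone.

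The shallow library, which played no part in picking these IDs, argues against an event in the strain F rapeseed library alone. Of the 57, 96.5% (55) were also listed at 0 in strain F on fishmeal, against 4.04% of IDs present in all deep libraries and matched on level in strain A. Length, which also sets how many reads an ID has, was not matched, so shorter IDs could raise the first share. Of the 66, 42 (63.6%) were above 0 there, against 10.3% of the 5434 IDs listed at 0 in both strain A libraries and under 10 in strain F on rapeseed. The 5434 include the 1585 IDs listed at 0 in all 4 libraries, which lowers their share, and were not matched on level or length. For IDs whose component had other IDs, the component's summed level was compared on rapeseed. It was at least 2-fold apart the same way for 79.5% (31 of 39) and 73.9% (34 of 46). The sum includes the limited ID and is of FPKM, which is scaled by length, so reads moved to a longer ID would lower it. These shares therefore cannot tell whether reads were assigned to another ID of the same assembly component, and that stays open. The remaining 18 and 20 IDs had no other ID in the component, and reads assigned to other components were not examined. A difference between the strains in gene content or expression, and a sequence difference from the reference used for mapping that would keep reads of 1 strain from aligning, may each give such zeros, and no sequences were at hand to tell them apart.

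In strain A the median log2 diet fold of IDs of mean level 1000 or more exceeded that of IDs of level 1 to 10 by 0.52 (95% bootstrap interval over IDs 0.49 to 0.57), and the former class held 62.5% of the summed level on fishmeal and 67.1% on rapeseed. A library factor moves every ratio of the pair alike and could make a gap only through the pseudocount, which damps it in low IDs, but without a pseudocount, over IDs above 0 in both libraries, the gap was 0.56 (0.52 to 0.60). With the pseudocount kept and the factors divided out it was 0.38 (0.35 to 0.42). The medians of the high and low class were then 0.06 and -0.33, in place of 0.49 and -0.04 on the deposited scale. Which class moved therefore depends on the scale. The intervals resample IDs of 1 pair of libraries and do not measure the spread between libraries. Setting the classes from the strain F rapeseed library, which is outside the pair, left a gap of 0.48 (0.45 to 0.52). The estimated depth of the rapeseed library was 1 times that of the fishmeal library (0.983 from values over 2). That estimate came from a search limited to ratios near 1, and the rapeseed library had more IDs listed at 0 (11105 against 8810). A difference of depth is therefore not set aside. Diet, the fish that entered each library and RNA quality also remain open and untested, with 1 library per diet.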
